A study of Mus musculus with 4 samples.

How the data were processed

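Single-cell RNA libraries of CD45-enriched cells were analysed from the lungs and blood of mice with an intrasplenic injection of B16F10 melanoma cells or saline, splenectomy and a subcutaneous B16F10 tumour. Per the labels' protocols, lungs were homogenised through a filter and passed over live/dead columns, blood cells were collected by density centrifugation, and libraries were sequenced on an Illumina NovaSeq. The design text of the series names commercial kits for the CD45 enrichment where the protocols name density centrifugation for blood, and which step was used on which tissue is unclear. The number of mice behind each library is not given in the sources used here. The deposited values are raw UMI counts per gene and barcode for 32285 genes, with no normalisation by the authors, in 1 matrix per library. Per the submitters' processing notes, Cell Ranger 7.0.0, the GRCm38.p6 genome build, Seurat 4.3.0.1 and R 4.3.1 were used, and the role of each step is not given in the sources used here. The smallest UMI total of a barcode was 500, 500, 501 and 500 in the lung metastasis, lung sham, blood metastasis and blood sham matrices, so barcodes below that depth were not analysed here.

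Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept. In the order above, 56.9%, 59.3%, 52.3% and 36.7% of barcodes had fewer than 200 genes, and over 99% of those consisted mainly of haemoglobin transcripts. Doublets were called per library with Scrublet in scanpy 1.11.5 (expected rate 10%). Its automatic threshold marked 0.48% of the cells of metastasis blood, so a common score of 0.3 was set after the data were seen, which removed 394, 689, 114 and 755 cells (2.95%, 4.88%, 1.33% and 5.79%). The 47169 cells left were normalised to 10000 UMIs, log-transformed and clustered together on 2000 variable genes without mitochondrial, ribosomal, haemoglobin, immunoglobulin or T cell receptor segment genes, with 30 principal components, 20 neighbours, Leiden resolution 1 and no batch integration. Clusters were named from 22 fixed marker lists: a name needed at least 3 markers of the class at 20 CPM or more and at least 2-fold above other clusters, with details of the naming set after the clusters were seen, and clusters without support stayed unnamed. Neutrophil-like cells fell into 3 of 32 clusters, and the same 4196 cells were neutrophil-like at resolution 2, with 41 clusters. Cluster names were rebuilt here and need not be those of the authors.

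UMIs were summed over the cells of a class in each library and scaled to 1000000 UMIs of the class (CPM), haemoglobin included. A gene was measured in a comparison with at least 100 UMIs over both libraries and a mean CPM of at least 10. With 1 library per group no test across samples could be made, cells were not used as replicates, and no p-value was computed. Log2 ratios carry the exact conditional binomial 95% interval of a pair of Poisson counts, shares carry exact Clopper-Pearson intervals or, at 0 cells, the limit that 3 counts allow, and a gene with 0 UMIs in a library was set to a floor of 3 counts, which gives a bound. Named genes in neutrophil-like cells were the 12 highest and 12 lowest log2 ratios among measured genes at 2-fold or more whose interval excluded equality. Their CPM also had to be at least 0.25 of the highest CPM of any other class in the library where the gene was higher, to limit the naming of free RNA of other cells. Haemoglobin counts in that CPM, so the rule is weak against classes rich in it, such as platelet-like cells of metastasis blood (78.5%). Ribosomal, mitochondrial, haemoglobin and immunoglobulin genes and unnamed gene models were left out of the named genes. Other classes with at least 100 cells in both libraries had 5 in each direction, and lung against blood 8, printed where both arms named them. Il1b, Il1a, Il1rn, Il1r1, Il1r2, Cxcr2, Cxcr4, Cd274, Arg1 and S100a8 were always reported. Further genes came from 24 fixed gene lists, as the members with the largest absolute log2 ratio, and the free RNA rule was not applied to list members. Some genes that these rules select are not reported here. A list's members were counted at 1.5-fold or more with an interval excluding equality, and the median log2 ratio of a list with 3 or more measured genes was placed as a percentile among 10000 random lists of the same size matched on mean CPM, which describes these libraries only.

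The groups, comparisons, gene lists, marker lists, filters, naming rule for genes and most alternatives were chosen before the data were examined. The alternatives were stricter (400 genes, 5% mitochondrial) and looser (100 genes) cell filters, doublets kept, resolution 2, and a class per cell from its own marker UMIs, whose rule was revised after its overlap with the clusters was seen. The others were scaling by the median of gene ratios or without mitochondrial, ribosomal, haemoglobin and the 20 most abundant genes, the mean of each cell's CPM, the free RNA rule for all genes, minimum UMI counts of 20 or 500, and cells thinned to 500 or 1000 UMIs. The share among cells that were not erythroid-like, cells without Pf4 or Ppbp, cells with at most 5% haemoglobin, and cluster 10 alone were added after seeing the data, as were cluster 14 alone for blood classical monocyte-like cells, and shares of other classes among all kept or non-erythroid cells or with clusters at resolution 2, and the free RNA rule for the number of genes in other classes. The procedure was tested on simulated Poisson counts with lung and blood class sizes. Both arms were drawn from a shared profile apart from the set genes. Differences between cells, mice or libraries and free RNA were not simulated, so the test covers counting error only. Of set genes that stayed measured, 93.6% of 78 at a log2 ratio of 1.5 and 100% of 59 at 3 were recovered among 2589 genes for lung. For blood these were 98.9% of 87 and 100% of 74 among 5536 genes, where 3 of 5375 unchanged genes passed. Set genes that fell below the limits for a measured gene were not counted. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Gene positions were taken from a GENCODE vM21 annotation of GRCm38.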

Results

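The data were 4 droplet libraries of single-cell RNA from the lungs and blood of female C57/Bl6 mice 6 to 8 weeks old, enriched for CD45-positive immune cells. On day 0 the mice received either 800000 B16F10 cells, a mouse melanoma line, or saline into the spleen, and the spleen was then removed in both arms. Every mouse also carried a subcutaneous tumour started from 250000 B16F10 cells, and tissue was taken on day 7. Blood leaving the spleen passes through the liver, and the labels describe the injected arm as bearing liver metastasis. It is called the metastasis arm here and the saline arm the sham arm. The title of the series concerns the action of liver metastases on neutrophils through IL-1. The comparisons were therefore metastasis against sham in lung and in blood, for the number of neutrophils and for their transcripts. Each tissue and arm had 1 library, so no difference has a replicate check, and every interval and detection floor given covers counting error only.

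The lung metastasis, lung sham, blood metastasis and blood sham libraries held 31176, 36125, 18115 and 20975 barcodes with 127281060, 132540945, 112079231 and 116022872 UMIs. Haemoglobin transcripts made up 78.1%, 65.7%, 78.6% and 43.7% of these UMIs in the same order. After filtering, 12969, 13443, 8483 and 12274 cells were kept, with median UMI counts of 4072, 3131.5, 4766 and 4051 before doublets were left out.

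Neutrophil-like cells, defined by transcripts such as S100a8, S100a9, Csf3r, Cxcr2 and Retnlg, took a larger share of the metastasis library than of the sham library in both tissues. In lung they were 1281 of 12969 cells, 9.88% (95% exact binomial interval 9.37 to 10.4), against 55 of 13443 cells, 0.409% (0.308 to 0.532), a 24.1-fold higher share (18.4 to 32.2). In blood they were 2425 of 8483 cells, 28.6% (27.6 to 29.6), against 435 of 12274 cells, 3.54% (3.22 to 3.89), an 8.07-fold higher share (7.28 to 8.95). Among cells that were not erythroid-like, the shares were 17.1% against 0.437% in lung and 44.4% against 3.67% in blood, or 39.0-fold (29.8 to 52.1) and 12.1-fold (10.9 to 13.4) higher. The class held 3 clusters. Cluster 9, of 1324 cells, had 1265 from metastasis lung and 53 from sham lung. Cluster 10, of 1076 cells, had 630 from metastasis blood and 430 from sham blood, and 1792 of the 1796 cells of cluster 8 came from metastasis blood. At resolution 2, a neutrophil-like cluster of 1331 cells held 1330 from metastasis blood, with the platelet gene Pf4 first among its top 10 genes. Another, of 466 cells, held 463 from metastasis blood and was led by Ngp, Ifitm6 and Lcn2. Blood cells were collected by density centrifugation and lung cells after sequential dead-cell columns, and the recovery of neutrophils in these steps is not given in the sources used here. The labels describe the CD45 enrichment in more than one way, and which step was used on which tissue is unclear.

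**Figure D1:**
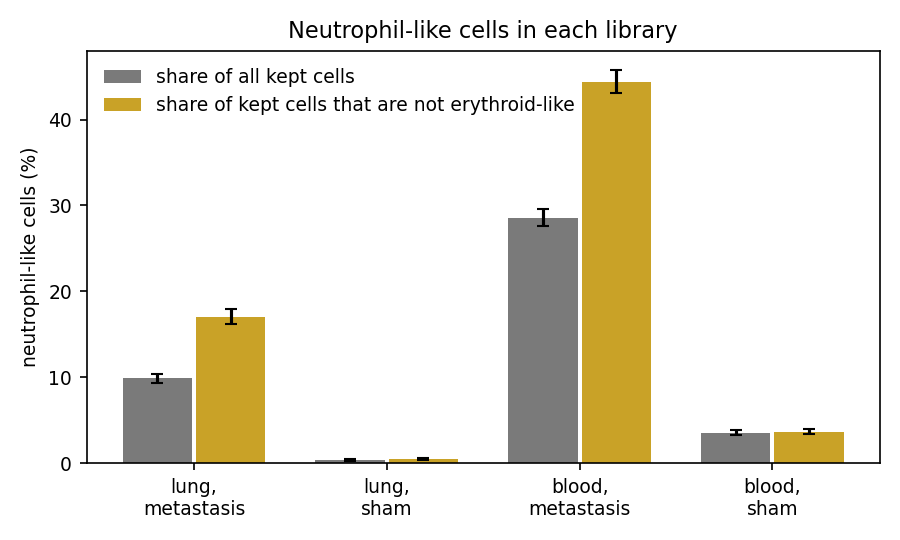
Bars give the share of kept cells that were neutrophil-like, in percent from 0, in each of the 4 libraries, with exact 95% binomial intervals that cover counting error only. The metastasis bars stand at 9.88% in lung and 28.6% in blood, and the sham bars at 0.409% and 3.54%.

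Erythroid-like and classical monocyte-like cells also took larger shares of the metastasis libraries, and B- and T-like cells smaller ones. Erythroid-like cells were 42.1% of metastasis lung against 6.38% of sham lung (6.60-fold, 6.14 to 7.11) and 35.6% of metastasis blood against 3.41% of sham blood (10.5-fold, 9.43 to 11.6). Their median gene counts were 267 and 248 in metastasis and sham lung and 253 and 1201.5 in blood, with a minimum of 200 for kept cells. Barcodes below that minimum were 56.87% and 59.27% of all barcodes in metastasis and sham lung, and 52.32% and 36.65% in blood. In each library at least 99.6% of them consisted mainly of haemoglobin transcripts, so the erythroid-like folds hold for kept cells only. Since shares add up to a fixed total, the other classes were set against the cells that were neither neutrophil-like nor erythroid-like. On that base, the classical monocyte-like share was 4.88-fold higher in metastasis lung (3.50 to 6.87; 126 against 52 cells) and 4.60-fold higher in metastasis blood (3.93 to 5.38; 361 against 295 cells). Of the blood monocytes, cluster 24, with 116 cells, was seen only in the metastasis library. Non-classical monocyte-like cells were 4.24-fold higher in lung (3.40 to 5.30). In lung, epithelial-like cells were 3.28-fold (2.63 to 4.10) and basophil- or mast-like cells 5.83-fold higher (2.76 to 13.4; 29 against 10 cells). Alveolar macrophage-like cells had a ratio of 1.28 (0.784 to 2.07) and endothelial-like cells one of 0.842 (0.619 to 1.13). T-like cells had a ratio of 0.790 in lung (0.750 to 0.831) and 0.900 in blood (0.821 to 0.985), and B-like cells 0.898 (0.852 to 0.947) and 0.815 (0.772 to 0.860). As shares of all kept cells, the classical monocyte-like ratios were 2.51 in lung and 1.77 in blood, and the non-classical, epithelial-like and basophil- or mast-like ratios in lung 2.18, 1.69 and 3.01. The T-like ratios were then 0.407 and 0.346, the B-like ones 0.463 and 0.314, and the alveolar macrophage-like and endothelial-like ones 0.662 and 0.434. For 3 other values the direction depended on the base. Non-classical monocyte-like cells in blood had a ratio of 1.41 (1.08 to 1.82) on the base without neutrophil- and erythroid-like cells, 0.813 (0.623 to 1.05) among cells that were not erythroid-like and 0.542 (0.415 to 0.701) among all kept cells. Platelet-like cells in blood were at 2.10 (1.82 to 2.43), 1.21 (1.05 to 1.40) and 0.810 (0.700 to 0.935) in the same order. NK-like cells in lung were at 1.09 (1.01 to 1.17), 0.905 (0.840 to 0.975) and 0.560 (0.520 to 0.603). In blood, NK-like cells were at 0.713 (0.513 to 0.974) on the first base and at 0.275 of all kept cells. With clusters at resolution 2, which named part of the T-like cells NK-like, the NK-like ratios on the first base were 1.01 in lung (0.949 to 1.08) and 0.858 in blood (0.683 to 1.07), both including equality. The T-like class included cluster 17, rich in haemoglobin transcripts, and cluster 19, led by interferon-response genes.

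In lung neutrophil-like cells, 3 genes of the stefin A family, Dennd3 and Rhov were among those higher in the metastasis library, and Spp1, Pak1, Cstb and Il1rn were lower. Stfa1, Stfa3 and Cstdc4, which belong to the stefin A family of cathepsin inhibitors, had log2 ratios of 3.27 (1.71 to 5.55), 3.52 (1.03 to 8.83) and 2.85 (2.16 to 3.63), with Cstdc4 at 662 against 92.2 CPM (UMIs scaled to 1000000 UMIs of the class). These genes are near-identical copies, so reads can be split between them and each value is uncertain. Dennd3, an activator of Rab GTPases in vesicle traffic, was at 69.3 against 5.42 CPM (log2 3.68, 1.18 to 8.99), and Rhov at 65.1 against 5.42 CPM (3.59, 1.09 to 8.90). Armc7 (3.28), the keratin gene Krt81 (3.20) and Atp6v0a1, a subunit of the proton pump that acidifies vesicles (2.80), followed. Ksr1, a scaffold of the Ras-MAPK pathway (2.75), Ctnnbip1, an inhibitor of beta-catenin (2.74), the histone acetyltransferase gene Kat2b (2.64; 1.56 to 2.66 over the alternatives) and the peroxisomal enzyme gene Phyh (2.63, 0.12 to 7.95) completed the 12 highest named genes. Of these 12, 10 rested on 1 UMI in the sham library, where 1 UMI was worth 5.42 CPM. Without cells over 5% haemoglobin Atp6v0a1 was at 0.48 and Phyh at 0.33, and with a class per cell from its own marker UMIs Ksr1 was at 0.89. On the lower side, Prkce, a protein kinase C, was at 24.6 against 108 CPM (−2.14, −2.86 to −1.36), but at a log2 ratio of 0.035 when each cell was classed by its own marker UMIs. Spp1, which encodes the secreted glycoprotein osteopontin, was at 54.9 against 201 CPM (−1.87, −2.39 to −1.32), and Pak1, a kinase of actin dynamics downstream of Rac and Cdc42, at 76.2 against 244 CPM (−1.68, −2.14 to −1.19). Jmy, an actin nucleation factor (−1.53; −1.61 to −0.98 over the alternatives), the RNA helicase gene Ddx24 (−1.52, but −0.45 with a class per cell), and the vesicle transport gene Sft2d2 (−1.39) were also lower. Raet1e, a ligand of the NK receptor NKG2D (−1.38), the transcription factor gene Usf2 (−1.34; −1.43 to −0.79 over the alternatives) and Ss18l2 (−1.22) followed. Homer1, a scaffold protein best known from synapses, was at 248 against 569 CPM (−1.20, −1.49 to −0.89). Cstb, the cathepsin inhibitor stefin B, was at 130.5 against 298 CPM (−1.19, −1.60 to −0.76), and Stag1, a cohesin subunit, at −1.19 (−1.86 to −0.44). Of 2730 measured genes, 100 were at least 2-fold higher and 72 at least 2-fold lower with intervals that excluded equality. With scaling by the median of gene ratios these counts were 71 and 93, and without cells over 5% haemoglobin 55 and 119. The sham class held 55 cells and 184463 UMIs, against 3334498 UMIs in the metastasis class. In data simulated with counting error only, 38 of 2452 unchanged genes passed the 2-fold rule. Differences between cells, mice or libraries were not simulated, so the share of false calls in the real data is not known. Haemoglobin took 24.3% of the UMIs of the metastasis class and 30.03% of those of the sham class.

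By fixed list, the secondary granule, NADPH oxidase and oxidative phosphorylation medians of lung neutrophil-like cells lay above those of most matched random lists, with a minority of members higher in the metastasis library. Of 17 measured secondary granule genes, 6 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.35, at percentile 98.3 of random lists matched on mean CPM. That median was 0.063 without cells over 5% haemoglobin and 0.091 with a class per cell, and 0.55 with the mean of each cell's CPM. A range given after a percentile is that of the median over the alternatives that could move it. Among the list's genes were Orm1, an acute-phase protein (85.5 against 21.7 CPM, log2 1.98), and Anxa1, a regulator of inflammation resolution (1855 against 1068 CPM, 0.80). The siderophore-binding Lcn2 (5627 against 3404 CPM, 0.72) and the bactericidal Pglyrp1 (0.71) were others. In the tertiary granule and mature neutrophil list, 5 of 28 genes were higher and 0 lower (median 0.20, percentile 88.4; 0.088 without cells over 5% haemoglobin), with Asprv1 at 2.54, Stfa2l1 at 0.85 and the resistin-like Retnlg at 17504 against 9785 CPM (0.84). The acute phase and STAT3 list had 4 of 18 higher and 0 lower (0.18, percentile 78.3; range 0.096 to 0.36), led by Orm1 and by Lrg1 (462 against 179 CPM, 1.37). Oxidative phosphorylation genes had 4 of 30 higher and 0 lower (0.32, percentile 98.8), with Cox4i1 at 322 against 157 CPM (1.03), but the median was −0.13 without cells over 5% haemoglobin. Ndufs6 was at 1.03 with an interval that included equality (−0.55 to 3.33). The NADPH oxidase and antioxidant list had 3 of 17 higher and 0 lower (0.38, percentile 99.4; range 0.19 to 0.39), including the oxidase subunit Ncf4 (0.87), Prdx5 (0.68) and Gpx4 (0.64). Glycolysis and hypoxia genes had 5 of 21 higher and 1 lower (0.21, percentile 93.7; range 0.115 to 0.22), with the lipid droplet gene Hilpda at 129 against 27.1 CPM (2.25), Gapdh at 0.91 and Vegfa at −0.82. Pfkfb4, also at −0.82, had an interval that included equality (−1.675 to 0.17).

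In the same lung cells the NF-kB response, IL-1 and immediate early lists had medians between −0.17 and 0.07. The NF-kB response list had 1 of 25 genes higher and 2 lower (median −0.09, percentile 14.2; range −0.17 to 0.095), and its median was 0.095 when each cell was classed by its own markers. The chemokine Ccl4 was at 70.2 against 27.1 CPM (1.37) and the prostaglandin synthase Ptgs2 at 323 against 623 CPM (−0.95). Of the 11 IL-1 and inflammasome genes measured, 2 were lower and 0 higher (0.07, percentile 45.5; range −0.14 to 0.20, with the other sign under 3 of 9 alternatives). Those were the receptor antagonist Il1rn (−1.10) and the signalling kinase Irak2 (163 against 293 CPM, −0.84). Immediate early and dissociation stress genes had 0 of 24 higher and 3 lower (−0.17, percentile 1.20; range −0.33 to −0.096), with Atf3 at −0.76 and Ppp1r15a at −0.71. The suppressive or tumour-associated list had 2 of 16 higher and 4 lower (−0.0009, percentile 43.1; range −0.087 to 0.24, with the other sign under 7 of 10 alternatives). In it Spp1 and Cstb were lower and the galectin Lgals3 was higher (687 against 347 CPM, 0.99), and Bsg was at 0.97 with an interval that included equality (−0.17 to 2.44). Trafficking and adhesion genes had 0 of 18 on either side (−0.09, percentile 24.3; range −0.22 to 0.050). The type I interferon list had 0 of 17 higher and 2 lower (0.10, percentile 44.4; range 0.017 to 0.36), namely Ifi27l2a (−0.76) and Isg15 (−0.71). The interferon gamma list had 0 of 4 on either side (−0.12, percentile 31.7; range −0.21 to 0.27) and MHC class I 0 of 10 (−0.03, percentile 35.4; range −0.115 to 0.16). Chemokines and cytokines had 1 of 7 higher and 1 lower (0.24, percentile 74.7; range 0.14 to 0.71). Apoptosis and survival had 1 of 11 each way (0.11, percentile 44.5; range −0.017 to 0.24), with Xiap at 1.99. Lipid handling had 0 of 9 higher and 1 lower (0.20, percentile 55.2; range −0.21 to 0.39). Proliferation genes had 2 of 5 higher and 0 lower (0.51, percentile 89.0; range 0.10 to 0.51), of which the ubiquitin-conjugating enzyme gene Ube2c rested on 1 sham UMI. The lists made for lymphocytes had 7 or fewer measured genes each. Naive and memory T cell genes had 0 of 7 higher and 2 lower (−0.21, percentile 14.5; range −0.43 to 0.044). Cytotoxic effector genes had 1 of 3 higher and 0 lower (1.28, percentile 99.8; range 0.63 to 1.40), and inhibitory receptor and exhaustion genes 0 of 3 on either side (−0.14, percentile 8.76; range −0.33 to 0.18).

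In blood neutrophil-like cells, most measured secondary granule genes were higher in the metastasis library, and most NF-kB response and immediate early genes were lower. Chil3, a chitinase-like protein of immature neutrophils, was at 1494 against 25.2 CPM (log2 5.89, 5.43 to 6.39). Ngp, neutrophilic granule protein, was at 5405 against 218 CPM (4.63, 4.48 to 4.79), and the interferon-induced transmembrane gene Ifitm6 at 2456 against 133 CPM (4.21, 4.01 to 4.41). The metallothionein Mt1, a metal-binding stress protein, was at 386 against 0.662 CPM (9.19, 6.71 to 14.5; 1 sham UMI). The stefin family genes Stfa2 (237 against 4.64 CPM, 5.67) and Cstdc5 (193 against 5.30 CPM, 5.19) were also higher, and are uncertain because of near-identical copies. The prion protein gene Prnp was at 71.6 against 1.99 CPM (5.17, 3.62 to 7.45). Bcl2l15 (6.19, 3.70 to 11.5) and Olfr1033 (4.99, 2.49 to 10.3), an annotated olfactory receptor, rested on 1 sham UMI, as did Lipg, endothelial lipase (5.49, 3.00 to 10.8). Cox6b2, a cytochrome c oxidase subunit, rested on 2 sham UMIs (4.60, 2.73 to 7.65) and is among the top 10 genes of the erythroid-like cluster 3. Gstt1, a glutathione transferase, had 532 UMIs against 0 and was at least 32.0-fold higher against a floor of 3 counts. It is one of 17 genes specific to platelet-like cells of that library, at 74.6 in neutrophil-like against 616 in platelet-like cells per 1000000 non-haemoglobin UMIs, and within cluster 10 its bound was a log2 ratio of 0.69. In sham blood Gstt1 was at 0 in neutrophil-like and 2.35 in platelet-like cells, so the platelet-like cells differed between the arms as well. On the lower side, Ptgs2, the inducible cyclooxygenase, was at 50.6 against 558 CPM (−3.46, −3.63 to −3.29), and the endosomal sodium-proton exchanger Slc9a9 at 45.3 against 337 CPM (−2.90, −3.09 to −2.70). The hypoxia-responsive Ndrg1 was at 15.3 against 107 CPM (−2.80) and the transcription factor gene Mitf at 12.9 against 82.1 CPM (−2.67). Mpeg1, the pore-forming perforin-2, was at 32.7 against 179 CPM (−2.46), and Zfp608 at 91.1 against 498 CPM (−2.45). Acta2, a smooth muscle actin (−2.56), the unconventional myosin Myo1d (−2.55) and Mpzl3 (−2.55) were lower as well. Lypd6b (−2.44), the calcium channel subunit Cacnb2 (−2.42) and Haus8, of the augmin complex (−2.42), completed the lower set. The clusters were built from variable genes of the same cells, so values within a cluster are partly circular. Il1b is among the top 10 genes of cluster 10, and Retnlg, Ifitm6, Ngp and Lcn2 are among those of cluster 8. Within cluster 10, the one that both blood libraries filled, most of these ratios were smaller. There Chil3 was at 1.28, Ifitm6 at 2.13, Mt1 at 3.78, Stfa2 at 2.498, Cstdc5 at 3.08, Lipg at 2.01 and Cox6b2 at 1.498, while Ngp was at 5.80. Bcl2l15, Prnp and Olfr1033 had no ratio there, and without cells holding Pf4 or Ppbp Olfr1033 was at 1.63. Ptgs2, Ndrg1, Slc9a9, Mitf, Haus8 and Mpeg1 were at −2.02, −1.64, −1.38, −1.31, −1.27 and −1.14. Myo1d, Zfp608, Mpzl3, Acta2 and Lypd6b were at −0.99, −0.91, −0.85, −0.73 and −0.67, and Cacnb2 was at −2.42.

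Of 5562 genes measured in blood neutrophil-like cells, 344 were at least 2-fold higher and 507 at least 2-fold lower, and the median gene stood at a log2 ratio of −0.17. These counts moved to 453 and 335 with scaling by the median of gene ratios and to 366 and 309 with the mean of each cell's own CPM. They were 450 and 339 without cells over 5% haemoglobin, and 265 and 633 with doublets kept. Without the most abundant genes in the total they were 572 and 271, and the median gene was at 0.12. Within cluster 10, 51 genes were higher and 181 lower. UMIs of the class summed to 8374085 in metastasis blood and 1509998 in sham blood, with haemoglobin at 14.8% and 6.66% of them. Platelet transcripts Pf4 or Ppbp were seen in 45.8% (43.8 to 47.8) and 53.8% (49.0 to 58.6) of neutrophil-like cells, against 1.43% and 1.80% of B-like cells. The Pf4 level of neutrophil-like cells was nevertheless higher in metastasis blood, at 2984 against 570 UMIs per 1000000 non-haemoglobin UMIs. In platelet-like cells Pf4 was higher in metastasis blood as well, at 25629 against 4382.

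Of 17 measured secondary granule genes in blood, 16 were at least 1.5-fold higher in the metastasis library and 1, the lysozyme Lyz2, was lower at 991 against 1659.6 CPM (−0.74). The median log2 ratio of the list was 2.05, above every one of the 10000 matched random lists, and 0.99 within cluster 10. Besides Chil3 and Ngp, Olfm4, a glycoprotein of a neutrophil subset, was at 3.36 and Adpgk at 162 against 16.6 CPM (3.29). Lcn2 was at 4506 against 654 CPM (2.79), the antimicrobial peptide gene Camp at 2.76 and lactoferrin, Ltf, at 2.05. In the tertiary granule and mature neutrophil list, 8 of 29 were higher and 12 lower (−0.23, percentile 86.9; range −0.40 to 0.0525). Retnlg, at 23201 against 5028 CPM (2.21), and the collagenase Mmp8, at 811 against 248 CPM (1.71), were higher, and Slfn5 (−1.41) and Csf3r (−1.29) lower. The median of that list was above 0 in cluster 10, without the most abundant genes in the total and with the mean of each cell's CPM. The same held for the suppressive or tumour-associated list, with 7 of 20 higher and 6 lower (−0.27, percentile 48.5; range −0.28 to 0.085). In it, Prok2, a chemotactic peptide of neutrophils, had 262 UMIs against 0 (at least 15.7-fold higher), and Wfdc21 was at 3369 against 552 CPM (2.61). The acute phase and STAT3 list had 7 of 19 higher and 6 lower (−0.36, percentile 53.5; range −0.38 to −0.044), with the serum amyloid Saa3 at 499 UMIs against 0 (log2 at least 4.91) and Fgl2 at −1.60. Oxidative phosphorylation genes had 13 of 39 higher and 1 lower (0.43, percentile 100; range −0.15 to 0.71), led by cytochrome c, Cycs (1.54), and Atp5g1 (1.25), but the median was −0.15 within cluster 10. Interferon gamma genes had 4 of 12 higher and 1 lower (0.24, percentile 93.3; range 0.22 to 0.58), with the MHC class I activator Nlrc5 at 1.01 and the guanylate-binding Gbp7 at 0.83.

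NF-kB response genes had 3 of 25 higher and 14 lower in blood neutrophil-like cells, with a median of −1.06 at percentile 0 and of −0.46 within cluster 10. Besides Ptgs2, the NF-kB inhibitor Tnfaip3 was at 37.3 against 154 CPM (−2.05), the growth factor Csf1 at 96.1 against 357 CPM (−1.89) and the NF-kB subunit Relb at −1.85. The higher genes were Ier3, Ccl4 and Cflar. Immediate early and dissociation stress genes had 0 of 23 higher and 17 lower (−1.03, percentile 0), with a median of −0.68 within cluster 10. The transcription factors Atf3 and Fosb were at 64.7 against 334 CPM (−2.37) and 72.8 against 292 CPM (−2.003), and Egr1 and Fos at 86.3 against 305 CPM (−1.82) and 1267 against 2538 CPM (−1.003). Of 19 IL-1 and inflammasome genes, 1 was higher and 7 lower (−0.29, percentile 36.2; range −0.55 to −0.0079). The inflammasome adaptor Pycard was at 53.7 against 7.28 CPM (2.88), and the DNA sensor Aim2 (−2.06), Irak2 (−1.64) and the sensor Nlrp3 (278 against 844 CPM, −1.60) were lower. The type I interferon list had 2 of 31 higher and 13 lower (−0.44, percentile 5.59; range −0.50 to 0.11, the last within cluster 10), with Ifit3 at −1.96, Ifi204 at −1.42 and the nucleic acid sensor Zbp1 at 1.60. Apoptosis and survival genes had 3 of 18 higher and 8 lower (−0.47, percentile 6.67; range −0.72 to −0.18), with the pro-death Pmaip1 at −2.21 and the pro-survival Bcl2l1 at 1.59. Trafficking and adhesion genes had 4 of 20 higher and 7 lower (−0.25, percentile 65.2; range −0.41 to 0.036), including the sphingosine receptor S1pr4 (2.03), Cd44 (1043 against 2908 CPM, −1.48) and Ptafr (−1.47). Chemokines and cytokines had 1 of 12 higher and 5 lower (−0.42, percentile 20.1; range −0.63 to −0.13), with Il15 at −1.58. Lipid handling had 2 of 13 higher and 4 lower (−0.29, percentile 27.8; range −0.4999 to −0.0071), with the cholesterol exporter Abca1 at 2.19 and Apoe at −1.13.

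Of the other blood lists, 5 had medians whose sign turned with the scaling or the set of cells. Glycolysis and hypoxia genes had 5 of 26 higher and 9 lower (−0.17, percentile 74.6; range −0.17 to 0.115), with Slc16a3 at −1.29 and Gpi1 at 1.24. MHC class I genes had 1 of 15 higher and 4 lower (−0.18, percentile 56.5; range −0.32 to 0.099), with the light chain B2m at 622 against 1409.9 CPM (−1.18). NADPH oxidase and antioxidant genes had 5 of 22 each way (−0.09, percentile 86.3; range −0.24 to 0.197), with the oxidase subunit Cybb at 1.13 and the cystine transporter Slc7a11 at −1.55. Proliferation genes had 1 of 9 each way (0.18, percentile 83.2; range −0.10 to 0.46), and cytotoxic effector genes 2 of 5 higher and 1 lower (0.13, percentile 87.0; range −0.89 to 0.41). Inhibitory receptor and exhaustion genes had 0 of 4 higher and 2 lower (−0.74, percentile 7.76; range −0.75 to −0.14), with Nr4a3 at −1.90. Naive and memory T cell genes had 1 of 7 higher and 5 lower (−1.07, percentile 0.45; range −1.38 to −0.54). The MHC class II, primary granule and regulatory T cell lists had fewer than 3 measured genes in the neutrophil-like cells of both tissues.

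**Figure D2:**
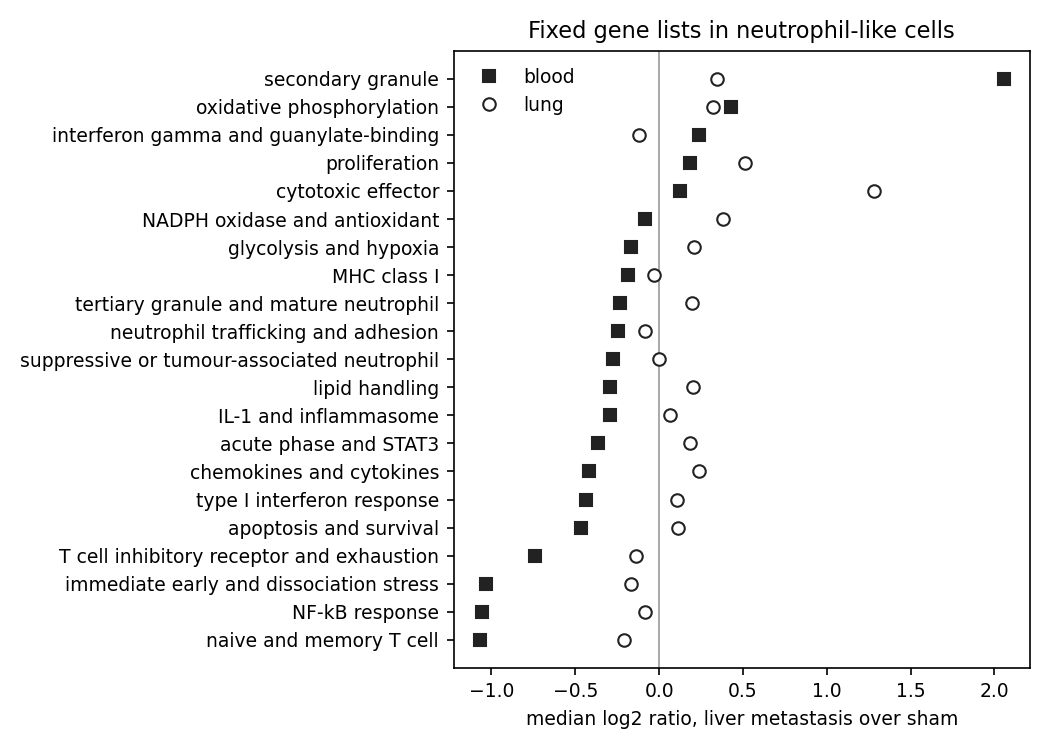
Points give the median log2 ratio, metastasis against sham, of the 21 fixed gene lists measured in neutrophil-like cells of both tissues, lung and blood marked apart. The secondary granule list stands at 0.35 in lung and 2.05 in blood, and the NF-kB response list at −0.09 and −1.06. Under other scalings the medians of the tertiary granule, suppressive, trafficking, glycolysis, MHC class I and NADPH oxidase lists in blood changed sign. So did that of the IL-1 and inflammasome list in lung. Further medians in both tissues turned with the mean of each cell's CPM or with another set of cells.

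Il1b was abundant in neutrophil-like cells of all 4 libraries, at close levels in both arms of lung and at a lower level in metastasis than in sham blood, where the difference was small within cluster 10. Il1b is itself among the top 10 genes of cluster 10, so its value there is partly circular. In lung it was at 3983 against 3936 CPM (log2 0.02, −0.09 to 0.13; other sign under 4 of 9 alternatives), and in blood at 2613 against 5903 CPM (−1.18, −1.21 to −1.14; −0.21 within cluster 10). The decoy receptor Il1r2, which binds IL-1 without signalling, was at 1795 against 1746 CPM in lung (0.04, −0.12 to 0.21; other sign under 5 of 9) and 2193 against 3209.9 CPM in blood (−0.55, −0.60 to −0.50; −0.88 to −0.27 over the alternatives). The receptor antagonist Il1rn was lower in both, at 93.9 against 201 CPM in lung (−1.10, −1.59 to −0.56) and 34.8 against 123 CPM in blood (−1.82, −2.09 to −1.54; −0.55 within cluster 10). Il1a had 51 UMIs against 3 in lung (−0.09, −1.72 to 2.24) and 6 against 0 in blood. The signalling receptor Il1r1 had 5 against 0 in lung and 26 against 2 in blood (1.23, −0.77 to 4.35). For both genes no difference was detectable at this depth. The calprotectin subunit S100a8 was at 63304 against 44410.0 CPM in lung (0.51, 0.48 to 0.54; 0.29 to 0.60 over the alternatives) and 51812.5 against 26585.5 CPM in blood (0.96, 0.95 to 0.98). The chemokine receptor Cxcr2, which guides neutrophil release and recruitment, was at 499 against 548 CPM in lung (−0.13, −0.42 to 0.17; −0.39 to −0.13 over the alternatives) and 1055 against 1238 CPM in blood (−0.23, −0.30 to −0.16; other sign under 3 of 10 alternatives). Cxcr4, which retains neutrophils in the marrow, was at 86.1 against 125 CPM in lung (−0.53, −1.15 to 0.15) and 169 against 423 CPM in blood (−1.32, −1.45 to −1.18). Cd274, the ligand PD-L1, was at 67.2 against 97.6 CPM in lung (−0.54, −1.23 to 0.24; other sign under 2 of 9) and 28.8 against 43.7 CPM in blood (−0.60, −1.001 to −0.19; −0.79 to −0.18 over the alternatives). Arg1 had 0 UMIs in neutrophil-like cells of every library, which at a limit of 3 counts allows up to 0.234% and 5.45% of cells with a UMI in metastasis and sham lung and up to 0.124% and 0.690% in blood.

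**Figure D3:**
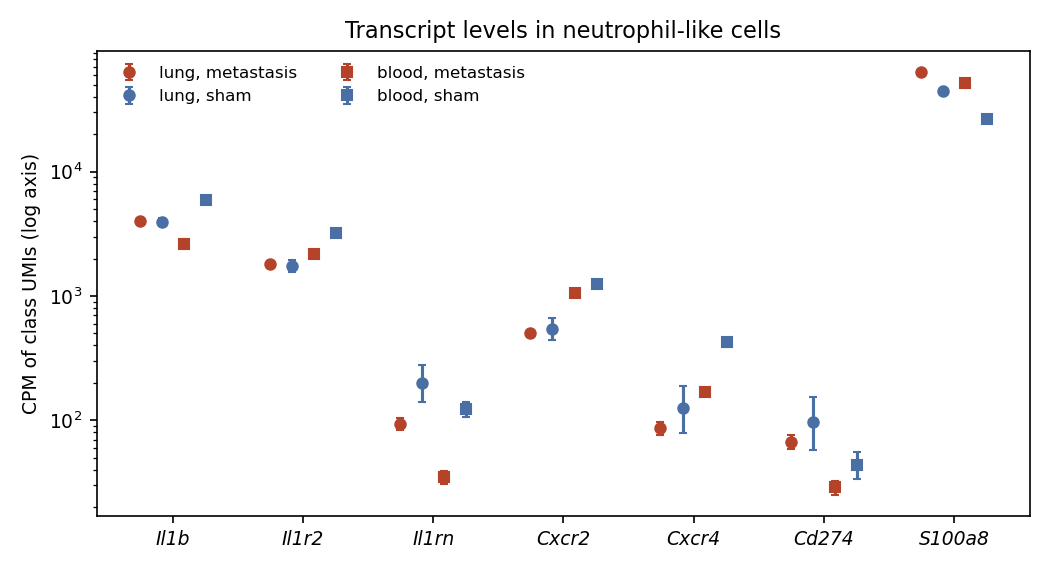
Points give the level of Il1b, Il1r2, Il1rn, Cxcr2, Cxcr4, Cd274 and S100a8 in neutrophil-like cells of each library, in CPM of the class on a log axis, with exact 95% Poisson intervals that cover counting error only. Il1b lies at 3983 and 3936 CPM in metastasis and sham lung and at 2613 and 5903 CPM in blood; the sign of the small Il1b and Il1r2 differences in lung and of Cxcr2 in blood turned under other scalings.

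Over all classes together, Il1b stood higher in the metastasis arm in both tissues. Among cells that were not erythroid-like, Il1b reached 923 against 55.3 UMIs per 1000000 non-haemoglobin UMIs in lung and 1330.1 against 199.95 in blood. Neutrophil-like cells held 80.1% and 35.5% of the Il1b UMIs of metastasis and sham lung, with non-classical monocyte-like cells next at 11.4% and 29.2%. In blood they held 93.1% and 81.8%, with classical monocyte-like cells next at 5.80% and 11.02%. An Il1b UMI was seen in 84.6% (82.5 to 86.6) and 83.6% (71.2 to 92.2) of lung and in 80.5% and 98.4% of blood neutrophil-like cells, against 1.80%, 1.21%, 0.873% and 0.446% of B-like cells. Median UMIs per cell were 1885, 2152, 2594 and 3028 in neutrophil-like cells and 1737.5, 2305.5, 2394 and 3471 in B-like cells. With each cell thinned to 500 UMIs, which left no neutrophil-like cell out, the shares were 70.4% and 70.9% in lung and 62.3% and 90.6% in blood. Thinned to 1000 UMIs, they were 76.4%, 77.6%, 72.5% and 96.9%, with 149, 6, 34 and 15 shallower cells left out.

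The genes discussed as IL-1 components are protein coding and lie on chromosomes 1 and 2 of the mouse genome (GRCm38, GENCODE vM21 annotation). Il1b (ENSMUSG00000027398) spans 129364570 to 129371139 on the minus strand of chromosome 2, with Il1a (ENSMUSG00000027399) beside it at 129299610 to 129309972 on the same strand. Il1rn (ENSMUSG00000026981) lies on the same chromosome and spans 24336853 to 24351494 on the plus strand. Il1r2 (ENSMUSG00000026073) spans 40074079 to 40125231 and Il1r1 (ENSMUSG00000026072) 40225080 to 40317257 on the plus strand of chromosome 1. That chromosome also carries Cxcr2 (74153989 to 74161246, plus) and Cxcr4 (128588199 to 128592293, minus). Cd274 lies on chromosome 19 (29367455 to 29388095, plus), S100a8 on chromosome 3 (90668978 to 90670035, plus) and Arg1 on chromosome 10 (24915221 to 24927484, minus). UMIs of each were summed over the whole gene.

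The metastasis ratios of lung and blood neutrophil-like cells, which share no library, were weakly related across genes. Over 2700 genes measured in both tissues, Spearman's correlation was 0.246 (0.204 to 0.282 from resampled genes) and Pearson's 0.277; genes are not independent replicates. At 2-fold or more, 26 genes were higher in both tissues, where independent lists would share 5.52, 12 were lower in both against 6.88, and 4 went opposite ways against 13.6. The log2 ratio in lung minus that in blood, which was not tested, was −5.55 for Chil3, −4.02 for Ngp, −2.70 for Camp and −2.10 for Ltf. It was 1.19 for Il1b, 0.78 for Cxcr4, 0.59 for Il1r2 and −0.45 for S100a8, and for these 8 genes the counting intervals of the tissues did not overlap. They overlapped for Il1rn, Cxcr2 and Cd274, with differences of 0.72, 0.10 and 0.06. These blood ratios are those of the whole class. Within cluster 10 Chil3 was at 1.28 and Il1b at −0.21, nearer to their lung ratios, while Ngp was at 5.80.

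Set against blood within each arm, the NF-kB response and secondary granule medians of lung neutrophil-like cells lay above those of nearly all matched lists. The scaffold gene Mpp7 was at 663 against 8.36 CPM in the metastasis arm (log2 6.31) and 493 against 20.5 CPM in the sham arm (4.59). The splicing factor gene Isy1 was at 290.3 against 13.02 CPM (4.48) and 363 against 22.5 CPM (4.01), and Vps37b, of the endosomal sorting machinery, at 4.25 and 3.69. Ctla2a was lower in lung, at 3.00 against 982 CPM (−8.36) and 5.42 against 1070.2 CPM (−7.63), and in metastasis blood it was one of 17 genes specific to platelet-like cells. In the metastasis arm, 21 of 28 NF-kB response genes were higher in lung and 3 lower (median 1.44, percentile 100), and in the sham arm 6 of 17 were higher and 2 lower (0.03, percentile 99.2). Secondary granule genes had 8 of 18 higher and 2 lower in the metastasis arm (0.46, percentile 99.9) and 11 of 13 higher and 0 lower in the sham arm (2.38, percentile 100). The median gene was lower in lung, at −0.58 in the metastasis arm and −0.87 in the sham arm, and clusters 9 in lung and 8 and 10 in blood filled the class. Tissue and cell preparation differed together, so no part of these values can be assigned to either.

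Among other classes, lymphocytes had few genes at 2-fold or more and blood classical monocyte-like cells had many, with fewer within the cluster that both blood libraries filled. Cluster 24 held 116 of the 361 metastasis cells and 0 sham cells, and cluster 14 the other 245 and all 295 sham cells. The whole class had 127 genes at least 2-fold higher and 131 lower in the metastasis library, against 34 and 102 within cluster 14. Under the free RNA rule, which leaves out genes under 0.25 of the CPM of another class, the whole class had 95 higher and 68 lower. In the whole class, the ectoenzyme gene Cd38 was at 104 against 3.94 CPM (log2 4.73) and the matrix protein gene Spon1 at 3.55, and within cluster 14 they were at 2.89 (1.98 to 3.92) and 2.45 (1.51 to 3.50). Lower there were Prg4, which encodes lubricin (1 UMI against 120, −6.97), the heat shock gene Hspa1a (−3.49), the lectin gene Cd209a (−2.58), Flt1 (−2.41) and lipoprotein lipase, Lpl (−2.38). Within cluster 14 Prg4 had 0 UMIs against 120, and Hspa1a, Cd209a, Flt1 and Lpl were at −3.15, −1.98, −2.22 and −1.78. Gstt1 (189 UMIs against 0, at least 60.3-fold), Gp1bb (3.22) and Lgalsl (3.15) were also higher in the whole class, and are among the 17 genes specific to platelet-like cells of that library. Within cluster 14, Gstt1 had 12 UMIs against 0, and Gp1bb (−0.22, −1.33 to 0.84) and Lgalsl (0.06, −1.002 to 1.08) had intervals that included equality. Lung non-classical monocyte-like cells had 40 genes higher and 32 lower, and 15 and 20 under that free RNA rule, with the inhibitory receptor gene Cd300lf at 97.9 against 12.04 CPM (3.02), the glucocorticoid-responsive Fkbp5 at 2.45, Anxa11 at 1.39 and Sos2 at 1.34. The B cell genes Aff3 (−3.88) and Bank1 (−3.64) were lower in them, as were Abhd17b (−1.30), Ets1 (−1.25) and Mef2c (−1.23). Lung epithelial-like cells had 9 higher and 47 lower, and 2 and 18 under the rule, with the surfactant protein Sftpc at 4637 against 12219 CPM (−1.40) and the fatty acid binding Fabp5 at −2.23. The desaturase Scd1 was at −1.64, Hnrnpa3 at −1.30, the sodium pump subunit Atp1b1 at −1.15, A2ml1 at 1.20 and Rexo2 at 1.04.

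Most of the genes at 2-fold or more in lung lymphocytes lay under 0.25 of the CPM of another class. Lung B-like cells had 10 genes higher and 4 lower, but 1 and 3 under the free RNA rule, with Cd200 at 1.01, Crisp3 at −1.06, and the immunoglobulin joining chain Jchain at 3 against 855 UMIs (−6.54). Lung T-like cells had 16 higher and 1 lower, but 2 and 0 under the rule, namely the peptide transporter Slc15a2 (1.08) and the guanylate-binding Gbp5 (1.03). Lung NK-like cells had 18 higher and 7 lower, but 1 and 2 under the rule, with Txnrd2 at 1.41, Rasal2 at −1.19 and Nek1 at −1.17. Blood B-like cells had 17 higher and 1 lower, and 12 and 1 under the rule, with the phosphatase Ptpn22 at 92.2 against 31.5 CPM (1.55), Slc15a2 at 1.48, Reln at 1.30, Ddit4 at 1.23, Zc3h6 at 1.10 and the heat shock gene Hsph1 at −1.53. Blood T-like cells had 26 higher and 11 lower, and 17 and 4 under the rule, among them Neb (48.3 against 4.21 CPM, 3.52), Gadd45g (2.47), the cytokine signalling inhibitors Socs3 (2.01) and Socs1 (1.4997), and Bcl3 (1.91). Hsph1 (−1.37), the co-chaperone gene Stip1 (−1.15) and Ttc32 (−1.0002) were lower. Erythroid-like cells of lung and blood and platelet-like cells of blood had 815, 1572 and 2011 genes at 2-fold or more. In these 3 classes the haemoglobin share of UMIs differed between the arms, at 88.3% against 83.6%, 91.8% against 75.2% and 78.5% against 26.7%. The median gene stood at −0.92, −3.34 and −2.29, so their genes are not compared between the arms.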

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

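The tests of red cell removal, of chaperone genes apart and of platelet transcripts were chosen after the result was seen, and the tests of the gene minimum, of handling and of cluster composition before; the rule that compares a value with the spread of resampled counts was added after.

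Melanoma transcripts (Mlana, Dct, Tyrp1 and Tyr), which no comparison above uses, were more frequent in metastasis blood than in its control. They summed to 18 UMIs over all barcodes of metastasis blood and to 2 in sham blood. Of the 18, 16 lay in 1 barcode that was classed as erythroid-like. In metastasis lung 5 UMIs lay in 1 barcode of the unnamed cluster 21, and sham lung had 2. No explanation of these counts was tested.

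The larger share of neutrophil-like cells in the metastasis libraries was weighed against filtering. If sham neutrophils had fallen below the minimum of 200 genes, a looser minimum of 100 genes should bring them back, but the share stayed 22.96-fold higher in lung and 6.21-fold higher in blood. Red cells counted in the total do not produce the larger share, which was 39.0-fold and 12.1-fold higher among cells that were not erythroid-like. That outcome was fixed by the shares. Erythroid-like cells took larger shares of the metastasis libraries, so leaving them out could only raise the fold. The comparison cannot speak to a step that changed the numbers of neutrophils and red cells together. Unequal loss of neutrophils in the columns, in density centrifugation or below 500 UMIs, differences between individual mice and an effect of liver metastases remain open, since each arm had 1 library per tissue. An effect of the metastases on neutrophil number is thus a hypothesis that these tests do not settle.

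The lower immediate early transcripts of blood neutrophil-like cells in the metastasis library (median log2 ratio −1.03, −1.09 to −1.01) were weighed against handling of the whole library. Handling should move the list in every class, but its median was 0.042 in B-like cells (−0.01 to 0.11), −0.027 in T-like cells (−0.11 to 0.07) and −0.22 in classical monocyte-like cells (−0.30 to −0.17), all above −0.52, the bound fixed as 0.5 of the neutrophil value, and without chaperone genes it was 0.105, 0.032 and −0.196 against −1.09 in neutrophil-like cells. For the chaperone genes of the list handling stays open, since their median was −0.84 in neutrophil-like cells and −0.496, −0.26 and −0.72 in B-, T- and classical monocyte-like cells, and the heat shock genes Hsph1 (−1.53 in B-like and −1.37 in T-like cells) and Stip1 (−1.15 in T-like cells), outside the list, were lower too. A different mix of clusters alone should leave little within cluster 10, but the median there was −0.68 (−0.79 to −0.61). That is smaller in size than the −1.03 of the whole class, so the mix may account for part of the pattern. The comparison is also partly circular, since the clusters were built on variable genes that can include members of the list. Handling that acts more on neutrophils than on other classes, the mix of clusters and an effect of liver metastases may each still contribute. They cannot be separated with 1 library per arm.

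Platelet transcripts in blood neutrophil-like cells were weighed as free RNA and as whole platelets. Free platelet RNA should reach all droplets alike, but the Pf4 level in neutrophil-like cells was 438 times that in B-like cells of metastasis blood and 122 times that of sham blood. Platelets carried with the cells should bring their transcripts in 1 ratio, and 100% of the 17 platelet-specific genes in metastasis blood and of the 8 in sham blood lay within a factor of 3 of the median share, which was 10.05% and 12.9% of the level in platelet-like cells. These values are consistent with platelets attached to neutrophils as a candidate explanation. Attachment in the animal, attachment after the blood was drawn and capture of a platelet and a neutrophil in 1 droplet were not told apart.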

How the results depend on the processing

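The share among non-erythroid cells and the sets limited to at most 5% haemoglobin, to cells without Pf4 or Ppbp or to cluster 10 were tests chosen after the results were seen, as were the values within cluster 14 and the shares of other classes on other bases or at resolution 2. The neutrophil-like share was higher in the metastasis library under every alternative, but the difference in percentage points, 9.47 in lung and 25.04 in blood, was 16.6 and 40.7 among non-erythroid cells, 16.0 and 41.4 with the stricter filter, 5.75 and 14.1 with 100 genes, and 23.1 in blood with a class per cell; the first 3 change the number of cells divided by. The number of genes at 2-fold or more, 172 in lung and 851 in blood, was 359 and 1582 at 20 UMIs and 31 and 353 at 500 UMIs, where the number of genes tested differs, 112 in lung under the free RNA rule, and 232 in blood within cluster 10, where fewer genes were measured. The lung genes, 100 higher and 72 lower, were 55 and 119 at 5% haemoglobin, 84 and 41 with a class per cell, 79 and 33 under the free RNA rule and 100 and 259 at 20 UMIs. For the remaining values the cause was not tested. The secondary granule median in blood, 2.05, was 2.45 with doublets kept, 2.56 with a class per cell, 2.38 at 5% haemoglobin, 0.99 in cluster 10, 2.34 without the 20 most abundant genes, 2.37 with the mean of each cell's CPM and 2.76 under the free RNA rule; in lung, 0.35, it was 0.55 with the mean of each cell's CPM, and 0.063 at 5% haemoglobin and 0.091 with a class per cell, both within its counting interval (0.041 to 0.51). The NF-kB median was 0.095 in lung with a class per cell and −0.46 in blood within cluster 10. The IL-1 median was −0.14 in lung and −0.17 in blood at 5% haemoglobin, and in blood −0.13 with scaling by the median of gene ratios and −0.0079 without the 20 most abundant genes. Spearman's correlation of the lung and blood ratios, 0.246, was 0.342 with doublets kept, 0.193 at 5% haemoglobin, 0.323 under the free RNA rule, 0.117 at 20 UMIs and 0.308 at 500 UMIs, and scaling cannot move it. Values whose counting interval excluded 0 turned sign as follows. With doublets kept, in blood, proliferation was −0.094 and Cxcr2 0.0084. With a class per cell, in lung, naive and memory T cell was 0.044 and Prkce 0.035. At 5% haemoglobin, oxidative phosphorylation in lung was −0.13 and glycolysis in blood 0.015. Within cluster 10, tertiary granule was 0.030, suppressive 0.085, type I interferon 0.11, glycolysis 0.067, oxidative phosphorylation −0.15 and proliferation −0.10. Without the 20 most abundant genes, in blood, tertiary granule and Cxcr2 were both 0.0525, trafficking 0.036, suppressive 0.0087 and glycolysis 0.115. With the mean of each cell's CPM, in blood, tertiary granule was 0.011, suppressive 0.068, glycolysis 0.065 and Cxcr2 0.030. Values whose interval included 0 also took the other sign. In lung these were the medians of the suppressive list under 7 alternatives, MHC class I under 5, interferon gamma under 4, IL-1 and lipid handling under 3 each, and NF-kB, trafficking, apoptosis and exhaustion under 1 each, and the ratios of Il1r2 under 5, Il1b under 4 and Cd274 under 2. In blood they were NADPH oxidase under 4, cytotoxic effector under 3 and MHC class I under 1. Apart from the IL-1, NF-kB and secondary granule lists, and with the turns of the first kind included, 273 of 372 list medians stayed within their interval, 82 moved and 17 turned; 495 of 601 named gene ratios stayed, 102 moved and 4 turned; and 23 of 80 shares of cells with a UMI stayed and 57 moved with thinning. Among other classes, turns were seen for the NK-like ratio in lung (0.560 of all kept cells, 0.905 of non-erythroid cells), the non-classical monocyte-like ratio in blood (0.542 and 0.813) and the platelet-like ratio in blood (0.810 of all kept cells), which follow from the number of cells divided by. In blood classical monocyte-like cells, 258 genes at 2-fold or more became 136 within cluster 14, where Il1r2 turned to −0.20 and Gp1bb to −0.22. Of 66 share ratios of other classes, 36 stayed within their interval, 25 moved and 5 turned; of 25 ratios and medians within cluster 14, 4 stayed, 19 moved and 2 turned. Resolution 2 left the same 4196 neutrophil-like cells and the free RNA rule cannot move a single gene or a list that keeps all its genes, so these values are left out of the counts. That rule, added later for other classes, left 4 of 14, 2 of 17 and 3 of 25 genes at 2-fold or more in lung B-, T- and NK-like cells, 20 of 56 in epithelial-like and 35 of 72 in non-classical monocyte-like cells, and in blood 13 of 18, 21 of 37 and 163 of 258 in B-, T- and classical monocyte-like cells. No paired analysis was possible because each tissue and arm had 1 library and no result came from a test. Depth limits lung most: with 184463 sham UMIs, 1 UMI was worth 5.42 CPM.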

Other observations

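The gene lists below were fixed before the data were examined; clusters 21 and 22 were singled out, and the tests within cluster 14 and with shares of all kept cells chosen, after the results were seen, and no explanation of these values was tested.

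Part of the granule and acute-phase genes stood higher in monocyte-like cells of the metastasis libraries, in blood by less within the cluster that both libraries filled. Of the 361 classical monocyte-like cells of metastasis blood, 116 were cluster 24, which held 0 sham cells and has Chil3, Saa3 and the platelet gene Pf4 among its top 10 genes. In the whole class, 12 of 27 measured genes of the tertiary granule and mature neutrophil list were at least 1.5-fold higher and 0 lower (median log2 ratio 0.53, percentile 100), with Retnlg at 2.90, the formyl peptide receptor Fpr1 at 2.18 and Il1r2 at 1.65. Within cluster 14, the one that both blood libraries filled, 2 of 25 were higher and 1 lower (0.03, percentile 74.5), with Retnlg at 0.34, Fpr1 at 0.70 (−0.11 to 1.52) and Il1r2 at −0.20. The acute phase and STAT3 list had 9 of 19 higher and 1 lower (0.58, percentile 100), with Lcn2 at 4.64, Wfdc21 at 4.06, Lrg1 at 2.84 and Saa3 at 2.29; within cluster 14 it had 6 of 19 higher and 1 lower (0.10, percentile 94.35), and these genes were at 2.72, 2.40, 2.26 and 1.21. MHC class II genes, which present antigen to helper T cells, had 0 of 9 higher and 7 lower (−1.07, percentile 0), with H2-Eb1 at −1.65, H2-Aa at −1.62, Cd74 at −1.53 and H2-Ab1 at −1.48. Within cluster 14 it had 0 of 9 higher and 5 lower (−0.63, percentile 0), and the 4 genes were at −1.05, −1.01, −0.93 and −0.88. The naive and memory T cell list, made for lymphocytes, moved alike in the whole class, with 0 of 10 higher and 5 lower (−1.08, percentile 0), and was at −0.97 within cluster 14. MHC class II transcripts are abundant in B-like cells, which made up 18.9% of metastasis blood against 60.2% of sham blood. In lung non-classical monocyte-like cells, the tertiary granule list had 10 of 17 higher and 0 lower (0.73, percentile 100), with Retnlg at 4.05 and Il1r2 at 3.42, and the acute phase list 5 of 13 higher and 0 lower (0.31, percentile 99.93). The interferon gamma list had 4 of 6 higher and 0 lower (0.80), with Tap1 at 1.05, Psmb9 at 0.99, Cd274 at 0.92 and Irf1 at 0.69. Retnlg, Il1r2 and Lcn2 are abundant in the neutrophil-like cells of the same libraries, which were more numerous in the metastasis arm. S100a8 in lung non-classical monocyte-like cells summed to 3502 UMIs against 152.

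In lung T- and B-like cells, the interferon gamma list had a median above those of nearly all matched random lists, with 2 members higher in each. In T-like cells the list had 2 of 18 genes higher and 0 lower (median 0.23, percentile 100), namely Gbp5 at 1.03 and Gbp2 at 0.68, and the granzyme Gzmb was at 1.01. Gzmb was not among the genes at 2-fold or more under the free RNA rule and is among the top 10 genes of the NK-like cluster 5. Resolution 2 named part of the T-like cells NK-like. In B-like cells the interferon gamma list had 2 of 15 higher and 0 lower (0.28, percentile 99.98), with Nlrc5 at 0.69 and Serpina3g at 0.67. Their type I interferon (0.24) and MHC class I (0.17) medians lay at percentiles 99.9 and 99.6. NK-like cells had 0 of 16 genes of the interferon gamma list on either side (−0.10, percentile 32.55), and the cytokine Ifng at 0.93 and the chemokine Ccl3 at 0.80. Their MHC class II list had 0 of 5 higher and 3 lower (−1.87), and those transcripts are abundant in B-like cells, which made up 15.4% of metastasis lung against 33.3% of sham lung. In blood T-like cells the acute phase list had 2 of 9 higher (0.28), with Socs3 and Bcl3. The inhibitory receptor and exhaustion list had 2 of 6 higher (0.48, percentile 100), with Ctla4 at 1.09 and Batf at 0.79.

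The unnamed cluster 21, led by genes of dividing cells, held 196 cells of metastasis lung against 30 of sham lung, 13.1-fold higher (8.92 to 20.005) among cells neither neutrophil-like nor erythroid-like and 6.77-fold higher (4.60 to 10.3) among all kept cells. Its top 10 genes included Car1, a carbonic anhydrase of erythroid cells, and haemoglobin took a median of 50.05% of the UMIs of its cells. Of the UMIs of the cluster, haemoglobin took 41.0% in metastasis lung and 10.4% in sham lung. The unnamed cluster 22 held 12 cells of metastasis blood against 192 of sham blood (0.235, 0.119 to 0.420), and 0.0904 (0.0459 to 0.162) among all kept cells.

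Between lung and blood in the metastasis arm, oxidative phosphorylation genes of neutrophil-like cells had 0 of 38 higher in lung and 16 lower (−0.51, percentile 47.2), and interferon gamma genes 1 of 11 higher and 7 lower (−0.94, percentile 10.2). Immediate early genes had 10 of 24 higher and 7 lower (0.19, percentile 99.7). In the sham arm immediate early genes had 5 of 23 higher and 13 lower (−0.83, percentile 22.8) and chemokines and cytokines 1 of 9 higher and 7 lower (−1.44, percentile 6.74).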
